A study of Mus musculus with 12 samples.

How the data were processed

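Total RNA of the mouse astrocyte line C8-D1A was taken up in Trizol and made into libraries with the NEBNext Ultra II kit, per the labels. There were 12 libraries in 4 groups of 3: control cells at 37 °C under 5% CO2, cells under 15% CO2, cells with 20 mM lactic acid, and cells in medium with 0.2 g/L NaHCO3, all collected after 24 h. Descriptions of replicates 2 and 3 give CO3 and CO4 in place of CO2, and reagent numbers rise by 1 with each replicate of the last 2 groups. Both were read as copying errors, and groups follow the treatment labels. The deposited table gives TPM (transcripts per 1000000) for 21959 Ensembl genes, with 1 column per library. Per the submitters' processing notes, reads were trimmed with fastp 0.22.0 and aligned with HISAT2 2.1.0 to GRCm39. The read counter, the annotation and the use of strand are not given in the sources used here. Each column sums to 1000000, so the values are shares of a library. No counts are listed, the depth of each library is unknown, and no counting intervals or detection floors could be given. Reads shared between near-identical genes (histone, ribosomal protein, Ifit3 and Ifit3b, Oas and Trim genes) may have been divided in ways the sources used here do not describe.

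Gene symbols were matched by Ensembl ID to GENCODE M21, an annotation of an older build. A symbol was found for 21851 IDs and not for 108, and 26 IDs repeated a symbol, which was kept for the ID with the highest mean TPM. Because the builds differ, no coordinates are given, and M21 served otherwise only for approximate transcript lengths and for sequence shared between transcripts of different genes, in stretches of a length that was shortened after a first run.

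Values were transformed as log2(TPM + 1). With this pseudocount of 1, log2 changes of genes at a few TPM are smaller than the log2 ratio of their TPM. Genes with at least 1 TPM in at least 3 libraries of any group were tested, which left 12326 genes. A group-means model was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3 (eBayes with a trend), and each of 6 contrasts between groups was tested on both sides with Benjamini-Hochberg adjustment within the contrast at a threshold of 0.05. A moderated F test of the 3 treatment coefficients gave the genes that differed among the 4 groups. Genes changed in all 3 treatments passed in the same direction in each contrast with control. Their number was set beside the overlap of independent lists. Correlations and covariances of log2 changes across genes were set beside 100 simulations of unchanged groups that shared the control libraries. In these each gene had the same spread in every library.

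A set of 30 gene lists with 605 members was written for astrocytes under acidification. They cover acid-base transport, metabolism, stress responses, the cell cycle, inflammation, astrocyte states and markers of other brain cell types, and all members were found in the table. Lists with at least 5 tested members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over lists within a contrast, with an estimated correlation beside it. Members past the threshold were counted over all genes tested and adjusted over the list alone. Summed TPM of mitochondrially encoded mRNAs and of ribosomal protein mRNAs were compared by exact two-sided permutation tests, where 3 libraries against 3 cannot give a p under 0.1.

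The genes named were set by rule. For each treatment against control these were the 10 highest and 10 lowest log2 changes past the threshold, with all 3 treated libraries outside the range of the 3 controls, a mean of at least 5 TPM in 1 of the groups, and no predicted or clone-based name. For each pair of treatments they were the 6 highest and 6 lowest by the same criteria. For genes changed in all 3 treatments they were the 6 in each direction with the largest smallest change. Each list described gave up to 4 members with the largest changes past the threshold, or, where no member passed, the 2 with the highest mean TPM. A fixed panel of 19 genes was always included. Some genes that the rule names are not reported here. Genes chosen otherwise are marked where they stand.

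Groups, contrasts, lists, tests, the naming rule and most alternative settings were fixed before the data were examined. The settings fixed then were log2(TPM + 0.1), no filter, a filter at 5 TPM, median-of-ratios scaling, quantile normalization, leaving out mitochondrial genes and the 10 most abundant genes, a fit of only the groups compared, robust and untrended eBayes, the replicate number as a block, and leaving out each library in turn. Chosen after seeing the data were every fit with control replicate 1 left out (12226 genes tested) together with the naming rule and the other settings on that fit, the removal of each library's trend with transcript length, the joint omission of control 1, 15% CO2 3 and lactic acid 3, and leaving out each library for the lists and the summed TPM. The 12-library fit remains the one reported first.

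Whether replicate numbers pair libraries across groups was checked on the residuals: 3 of 18 pairs with the same number correlated above 0.1 (range −0.145 to 0.462), and 3 of 12 libraries matched their own number best. They were treated as unpaired. The pipeline was tested on simulated data (15% CO2 against control, 12226 genes). With a simulated first control, 68.7%, 95.5% and 100% of genes changed by 0.5, 1 and 2 (log2) were called. Of 188 calls, 12 were false. With the deposited control 1 the shares were 47.8%, 89.6% and 98.5%, with 2 of 159 calls false. No call had the wrong sign. Rates for low genes or the real libraries may differ. All deposited columns were used.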

Results

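RNA of C8-D1A, an established mouse line of astrocytes (the glial cells that supply neurons with lactate and buffer their surroundings), was measured in 12 libraries, 3 in each of 4 groups. The design sets 3 ways of acidifying the cells beside an untreated control: raised CO2, added lactic acid, and medium low in bicarbonate, called low-NaHCO3 medium here. The pH reached in each group is not given in the labels used here, so the treatments cannot be matched by pH. Whether the 3 libraries of a group came from separate cultures is not stated either, and an n of 3 may count repeats of 1 culture. Each library listed 14531 to 17319 genes above 0 TPM. Libraries are named by group and replicate, so that CO2 1 is replicate 1 of 15% CO2. TPM values are given as mean ± SD of 3 libraries and log2 changes with the standard error of the fit, and a value with ± alone in parentheses is a log2 change. Genes named as the highest or lowest had all 3 treated libraries outside the range of the 3 controls, which chance alone gives for 10% of genes.

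Control replicate 1 held transcripts of brain cell types that the other 11 libraries almost lacked. The genes given for it here and in the figure, apart from Vim, were chosen after their values were seen. Snap25, a synaptic gene of neurons, stood at 603 TPM there and at no more than 0.0363 TPM elsewhere. Gad1, the enzyme that makes GABA, stood at 338 against at most 0.175 TPM, Mobp, a myelin gene, at 177 against at most 0.0390 TPM, and Hbb-bs, a haemoglobin gene of red blood cells, at 249 against at most 0.326 TPM. Genes of mature astrocytes followed, with Slc1a2, a glutamate transporter, at 316 against at most 0.416 TPM and Aqp4, a water channel, at 45.3 against at most 0.356 TPM. Of the marker lists, 12 of 13 neuron genes, 10 of 11 oligodendrocyte genes, 10 of 12 microglia genes, 10 of 12 endothelial and mural genes and 18 of 20 astrocyte identity genes were higher in control 1 than in every other library. Vim, an intermediate filament gene that the line expresses strongly, stood at 1000.4 TPM there and at 1327 to 2678 TPM elsewhere. Its Spearman correlation with the other libraries, across genes, ran from 0.817 to 0.881, against 0.929 to 0.998 among those 11. Values with control 1 left out, a setting chosen after seeing the data, stand beside the 12-library values below for some results only. Where none is given, the control mean, SD and log2 change include control 1 and may be shifted by it.

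**Figure D1:**
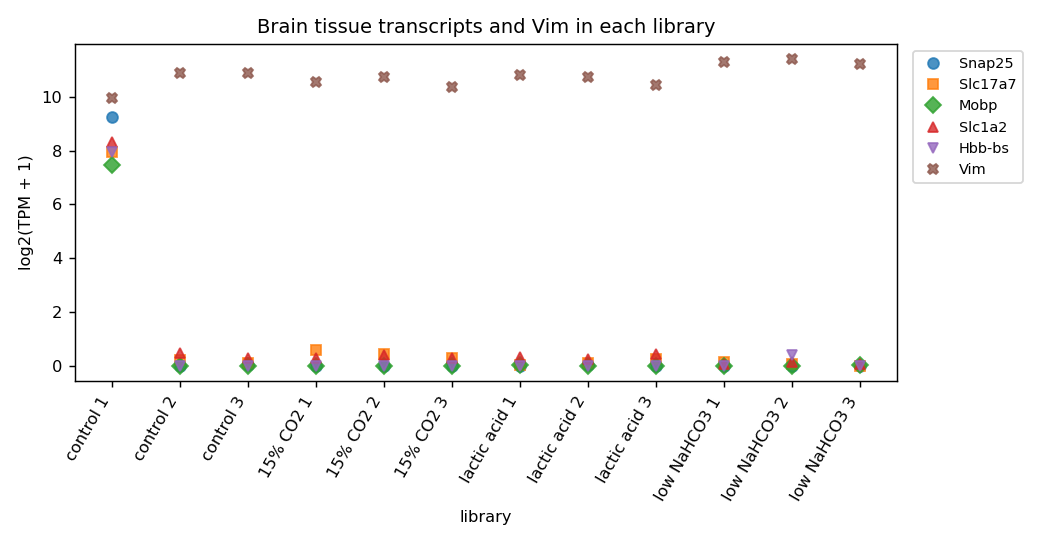
Level of 6 genes in each of the 12 libraries, as log2(TPM + 1), by group on the horizontal axis; each point is 1 library. Snap25, Slc17a7, Mobp, Slc1a2 and Hbb-bs were high in control 1 alone, with Snap25 at 603 TPM, while Vim was lower there than in the other 11 libraries.

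The groups differed in 6597 of 12326 genes tested by limma's moderated F test (9099 of 12226 without control 1). Against control, 166 genes changed under 15% CO2, 492 with lactic acid and 6758 in low-NaHCO3 medium. With control 1 left out these became 902, 1972 and 7786. The first 166 and 492 were all called in both fits, and so were 6438 of the 6758. The larger counts rest on 2 controls. When control 2 was left out as well, the counts were 56 for 15% CO2 and 229 for lactic acid, and with control 3 left out instead they were 206 and 442, with the lone control taken to vary like the other groups. The 902 became 345 without CO2 1 and 554 without CO2 3. Changes of at least 1 on the log2 scale numbered 50 up and 0 down under 15% CO2, 38 up and 15 down with lactic acid, and 576 up and 1687 down in low-NaHCO3 medium. The median log2 change of all tested genes in low-NaHCO3 medium was −0.20. It was −0.037 under median-of-ratios scaling, 0.0046 under quantile normalization and −0.29 without the mitochondrial and 10 most abundant genes, so list medians in that group are to be read against −0.20. The list tests carry a limit of their own: the same libraries split by other labels also gave list calls, up to 13 for 15% CO2 and up to 15 for each other treatment.

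**Figure D2:**
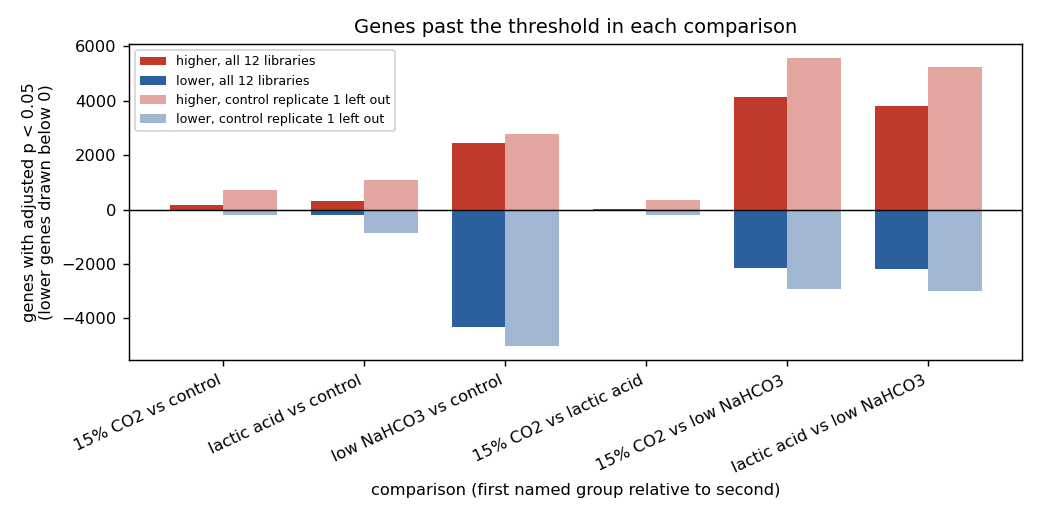
Number of genes higher and lower in each of the 6 contrasts (bars from 0), for all 12 libraries and with control 1 left out. Low-NaHCO3 medium gave 6758 and 7786 genes against control in the 2 fits, while the counts for 15% CO2 and lactic acid were 166 and 902 and 492 and 1972.

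Under 15% CO2, against control, genes of the interferon response rose together. Of 24 measured members of the interferon list, 20 rose, 22 adjusted over the list alone, and none fell. Ifit1 (ENSMUSG00000034459), an antiviral RNA-binding protein, rose by about 2 on the log2 scale (25.1 ± 5.81 against 5.59 ± 1.87 TPM, log2 change 1.999 ± 0.23, adjusted p = 0.0038). Irf7, a transcription factor that drives interferon genes, rose with it (11.2 ± 2.81 against 2.89 ± 0.499 TPM, log2 change 1.64 ± 0.22, adjusted p = 0.0078). Ifit3 (32.9 against 8.61 TPM, log2 change 1.89 ± 0.34), Rtp4 (24.3 against 5.55 TPM, log2 change 1.97 ± 0.23), Oasl2 and Usp18 (1.91 and 1.74) belong to the same list. Outside it, the interferon-inducible genes Oas2 (2.03 ± 0.28), Oas1b (1.80 ± 0.18) and Zbp1 (1.61 ± 0.27), a nucleic acid sensor, were also among the 10 highest. The list had a median log2 change of 1.34, adjusted p = 3.17e-31. It had adjusted p = 0.09 with an estimated correlation, and its median without control 1 was 1.32.

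15% CO2 also raised Myog, Klhl41 and Mymk, which are known from muscle and are named here after their values were seen. No list of muscle genes was tested. Myog, the muscle regulator myogenin, stood at 31.0 against 10.7 TPM, log2 change 1.46 ± 0.22, Klhl41, a sarcomere gene, at 20.6 against 7.39 TPM, log2 change 1.36 ± 0.23, and Mymk, which drives the fusion of myoblasts, at 12.5 against 5.48 TPM, log2 change 1.06 ± 0.20. Among the 10 highest was also Igfbp5 (ENSMUSG00000026185), a binding protein for insulin-like growth factors (263 ± 12.6 against 89.1 ± 38.9 TPM, log2 change 1.63 ± 0.29, adjusted p = 0.0215). Car9 (ENSMUSG00000028463), a carbonic anhydrase of the cell surface that hydrates CO2, rose (13.8 ± 0.585 against 6.71 ± 0.190 TPM, log2 change 0.94 ± 0.099, adjusted p = 0.0038). It was the 1 member of 19 that rose in the acid-base list and the 1 of 23 in the hypoxia list, with 4 and 4 adjusted over the list alone. In the matrix list 1 of 25 rose, over all genes and adjusted over the list alone. This was Fn1, which encodes fibronectin (596 against 330.0 TPM, log2 change 0.89 ± 0.19, adjusted p = 0.0441), and median-of-ratios scaling ended its call.

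Of the 8 genes that fell under 15% CO2, 3 belong to lipid synthesis. Cyp51 (ENSMUSG00000001467), an enzyme of the late cholesterol pathway, fell (30.5 ± 1.72 against 48.7 ± 3.79 TPM, log2 change −0.66 ± 0.11, adjusted p = 0.0169), as did its neighbour in the pathway Lss (log2 change −0.53 ± 0.087, adjusted p = 0.0156). Elovl6, a fatty acid elongase, fell too (log2 change −0.502 ± 0.077, adjusted p = 0.012). In the cholesterol list 2 of 24 fell, 17 adjusted over the list alone, and in the fatty acid list 1 of 12, 4 adjusted over the list alone. The cholesterol list had a median log2 change of −0.41, adjusted p = 5.29e-14. It had adjusted p = 0.09 with an estimated correlation. Without control 1, 13 of its members fell and its median was −0.45. The other genes that fell were Tfrc, the transferrin receptor (140.1 against 249 TPM, log2 change −0.82 ± 0.15), and Mt1, a metallothionein (171 against 253 TPM, log2 change −0.57 ± 0.098). Rbm3, an RNA-binding protein induced by cold, had a log2 change of −0.58 ± 0.11, Shroom2 of −0.49 ± 0.084 and Dynll1 of −0.40 ± 0.075.

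Camera called 11 lists for 15% CO2, 6 of them up, and none with an estimated correlation. Beside interferon and cholesterol these were matrix (median 0.31, adjusted p = 0.000524), fatty acid synthesis (median −0.16, adjusted p = 0.00309), A1-type reactive astrocyte (median 0.52, adjusted p = 0.0181) and p53 targets (median −0.19, adjusted p = 0.0455). With an estimated correlation they had adjusted p = 0.267, 0.267, 0.376 and 0.211. The rest were ER stress (median −0.11, adjusted p = 0.0456), hypoxia (median 0.20, adjusted p = 0.0456), mitosis (median 0.24, adjusted p = 0.0456), lysosome (median 0.16, adjusted p = 0.0456) and oligodendrocyte lineage (median −0.91, adjusted p = 0.0456). They had adjusted p = 0.806, 0.794, 0.877, 0.794 and 0.794 with an estimated correlation. No single member of the p53, ER stress, mitosis, lysosome and oligodendrocyte lists passed, over all genes or adjusted over the list alone, with all 12 libraries. Of 7 A1-type genes 1 rose, 4 adjusted over the list alone: Iigp1, which is itself induced by interferon (log2 change 1.59 ± 0.31, adjusted p = 0.0302). Without control 1 the test of the mitosis list turned down (median −0.092), and the lysosome and oligodendrocyte lists no longer passed.

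The other 15 lists tested for 15% CO2 had adjusted p from 0.265 to 0.871 with all 12 libraries. In the NRF2 list the glutathione transferase Gstm1 rose (441 against 309 TPM, log2 change 0.52 ± 0.083), and in the pan-reactive list Cxcl10, an interferon-induced chemokine, rose (9.72 against 3.15 TPM, log2 change 1.38 ± 0.19). In the ferroptosis and iron list Tfrc fell. With all 12 libraries no member passed over all genes in the glycolysis, TCA, integrated stress, DNA replication, heat shock, immediate early, A2-type, astrocyte identity, NFkB, mitochondrial mRNA and ribosomal protein lists. Median, mean and test differed in sign in the acid-base, integrated stress, DNA replication, heat shock and pan-reactive lists. Of the lists too small for camera, the endothelial and mural one held 1 gene that rose, Pdgfrb (27.8 against 17.4 TPM, log2 change 0.65 ± 0.11). The proton sensing, microglia and neuron lists held none.

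Of these 15 lists, 6 passed camera for 15% CO2 with control 1 left out, none with an estimated correlation. DNA replication (median −0.25, 2 of 26 fell), integrated stress (−0.28, 3 fell and 1 rose), NRF2 (−0.24, 5 fell and 1 rose), ferroptosis and iron (−0.16, 4 fell and 1 rose) and ribosomal protein (−0.29, with no single member that passed) went down. Astrocyte identity went up (0.29, 2 rose), with only 9 of its 20 genes high enough to test. In that fit 7 matrix, 5 hypoxia, 4 A1-type, 3 immediate early, 2 pan-reactive, 2 TCA and 2 acid-base genes rose, and 3 fatty acid and 3 ER stress genes fell. In the p53 list 3 fell and 1 rose. The glycolysis, lysosome and mitochondrial mRNA lists each held 1 gene that rose, and the heat shock list 1 that fell. Of the small lists, endothelial and mural held 2 genes that rose, proton sensing and microglia 1 each, and neuron 1 that fell.

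The count of 166 genes for 15% CO2 (158 up, 8 down) became 30 without CO2 1, 35 without CO2 2, 92 without CO2 3, 47 without control 2 and 902 (711 up, 191 down) without control 1. The balance of the latter was 766 up and 591 down under median-of-ratios scaling and 679 and 835 with the length trend removed. A limma fit of only these 6 libraries called 0 genes, with 1177 at an unadjusted p under 0.05 (1908 in the 12-library fit), and the replicate block gave 72.

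Lactic acid, against control, raised genes of the matrix and of the immediate early response. The highest log2 changes were those of Sh2d6 (16.8 against 3.58 TPM, log2 change 1.97 ± 0.19), Odf3l1 (62.3 against 15.7 TPM, log2 change 1.97 ± 0.24) and Cd68 (ENSMUSG00000018774), a lysosomal glycoprotein best known from macrophages (215 ± 31.3 against 55.7 ± 14.1 TPM, log2 change 1.95 ± 0.18, adjusted p = 0.00182). P2rx3 (ENSMUSG00000027071), an ATP-gated cation channel, rose (18.1 ± 1.39 against 4.37 ± 1.13 TPM, log2 change 1.85 ± 0.22, adjusted p = 0.00434). Also among the 10 highest were the small heat shock protein gene Hspb7 (1.51 ± 0.21), Mogat2 (1.42 ± 0.30), Pycr1 (1.39 ± 0.21), Selp (1.32 ± 0.17) and Pkp1 (1.22 ± 0.19). Of 25 matrix genes 5 rose, 8 adjusted over the list alone. Ccn1, a matricellular signal, rose most (504 ± 6.99 against 197 ± 57.5 TPM, log2 change 1.40 ± 0.18, adjusted p = 0.00658), and Fn1 rose too (724 against 330.0 TPM, log2 change 1.16 ± 0.19). Tnc rose by 1.07 ± 0.24 on the log2 scale, and by 0.71 without control 1. Of 18 immediate early genes 4 rose, while adjusted over the list alone 7 rose and 1 fell. They were Zfp36 (21.4 against 10.1 TPM, log2 change 0.99 ± 0.14), Dusp1 (0.81 ± 0.15), Klf6 (0.49 ± 0.11) and Myc (0.80 ± 0.20, and 0.51 without control 1).

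Cholesterol, fatty acid and ER chaperone genes fell with lactic acid. Of 24 cholesterol genes 10 fell, 20 adjusted over the list alone. Among them were Hmgcs1, which feeds the mevalonate pathway (40.5 ± 4.90 against 81.6 ± 23.6 TPM, log2 change −0.97 ± 0.20, adjusted p = 0.0283), Cyp51 (−0.87 ± 0.11) and Acat2 (−0.86 ± 0.15). Of 12 fatty acid genes 4 fell, 5 adjusted over the list alone. These were Elovl6 (−0.63 ± 0.077), the fatty acid synthase Fasn (57.7 against 88.1 TPM, log2 change −0.60 ± 0.10), the desaturase Scd2 (−0.46 ± 0.10) and Acly (−0.29 ± 0.071). Of 20 ER stress genes 5 fell, 7 adjusted over the list alone. Sdf2l1, which acts with the ER chaperone BiP, fell most (31.7 ± 6.81 against 91.9 ± 18.3 TPM, log2 change −1.51 ± 0.20, adjusted p = 0.00747), then Creld2 (65.1 against 139 TPM, log2 change −1.08 ± 0.18), Manf, a secreted ER stress protein (68.8 against 116 TPM, log2 change −0.74 ± 0.12), and Dnajc3 (−0.47 ± 0.091). The heat shock list held 3 of 16 that fell, the same number adjusted over the list alone: Hsph1 (−0.75 ± 0.069), Dnaja1 (−0.61 ± 0.10) and Dnajb1 (−0.32 ± 0.076). Among the 10 lowest were also Tfrc (102 against 249 TPM, log2 change −1.29 ± 0.15), Hist1h4i, a histone gene (16.2 against 47.7 TPM, log2 change −1.51 ± 0.37), and Myog (4.71 against 10.7 TPM, log2 change −1.06 ± 0.22). The others were Cox8b (−1.71 ± 0.34), Acyp2 (−1.59 ± 0.36), Wdr6 (−1.21 ± 0.28), the peptide hormone gene Apln (−1.08 ± 0.19) and Iqsec3 (−1.22 ± 0.30, and −0.76 without control 1).

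Interferon genes rose in part with lactic acid. Of 24 members 3 rose, 8 adjusted over the list alone: Rtp4 (12.9 against 5.55 TPM, log2 change 1.10 ± 0.23), Ddx58, a sensor of viral RNA (24.8 against 14.2 TPM, log2 change 0.77 ± 0.15), and Rsad2 (9.75 against 5.39 TPM, log2 change 0.76 ± 0.18). The list had a median log2 change of 0.46, adjusted p = 5.05e-08. It had adjusted p = 0.488 with an estimated correlation. Without control 1, 10 members rose and the median was 0.48. In the acid-base list 2 of 19 rose and 1 fell (3 and 1 adjusted over the list alone). Slc4a7, a sodium bicarbonate cotransporter, rose (45.4 against 27.6 TPM, log2 change 0.70 ± 0.10), as did Car9 (10.97 against 6.71 TPM, log2 change 0.63 ± 0.099), and the anion exchanger Slc4a2 fell (16.5 against 26.8 TPM, log2 change −0.65 ± 0.14). In the hypoxia list 3 of 23 rose: Car9, the ER oxidase Ero1l (0.76 ± 0.15) and the growth factor Vegfa (0.49 ± 0.11). Sox9, a glial transcription factor, was the 1 of 10 astrocyte identity genes that rose (51.2 against 29.97 TPM, log2 change 0.77 ± 0.12). Cd109 was the 1 of 5 in the A2-type list (203 against 95.0 TPM, log2 change 1.13 ± 0.19).

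Camera called 9 lists for lactic acid, 5 of them up, and none with an estimated correlation. Beside interferon they were cholesterol (median −0.505, adjusted p = 1e-13), ER stress (median −0.30, adjusted p = 0.000167), matrix (median 0.24, adjusted p = 0.00063) and immediate early (median 0.36, adjusted p = 0.000952). With an estimated correlation these had adjusted p = 0.111, 0.526, 0.488 and 0.111. The rest were integrated stress (median 0.23, adjusted p = 0.000952), fatty acid synthesis (median −0.20, adjusted p = 0.00968), glycolysis (median −0.36, adjusted p = 0.0121) and mitosis (median 0.23, adjusted p = 0.0185). Those had adjusted p = 0.744, 0.488, 0.488 and 0.761 with an estimated correlation. In the integrated stress list 2 of 25 rose, 3 adjusted over the list alone: Pycr1, an enzyme of proline synthesis, and the lipoprotein receptor gene Vldlr (0.69 ± 0.10). Without control 1 the integrated stress, mitosis and glycolysis lists no longer passed. The immediate early list then had a median of 0.52, 12 members that rose, and adjusted p = 0.00921 with an estimated correlation. No member of the glycolysis and mitosis lists passed with all 12 libraries, over all genes or adjusted over the list alone.

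The other 17 lists tested for lactic acid had adjusted p from 0.052 to 0.884 with all 12 libraries. Single members that rose in them were Gstm1 (0.37 ± 0.083), Npc1 (0.51 ± 0.093), Ccl7 (0.77 ± 0.17) and mt-Co2 (0.77 ± 0.17). Those that fell were Bax (−0.69 ± 0.16), mt-Nd3 (−0.84 ± 0.19), Tfrc, and Atp6v0d1 (−0.62 ± 0.15, but −0.40 without control 1). The TCA, DNA replication, pan-reactive, A1-type, oligodendrocyte and ribosomal protein lists held no member past the threshold over all genes in that fit. Median, mean and test differed in sign in the acid-base, pan-reactive and ribosomal protein lists. Of the small lists, microglia held Cd68 and endothelial and mural held Pdgfrb (0.46 ± 0.11), both of which rose, and proton sensing and neuron held none.

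Of these 17 lists, 4 passed camera for lactic acid with control 1 left out, none with an estimated correlation. DNA replication (median −0.30, 13 of 26 fell) and heat shock (−0.29, 5 of 16 fell) went down. A1-type (0.34, 2 rose) and astrocyte identity (0.48, 4 rose of the 9 tested among its 20 genes) went up. In that fit 17 cholesterol and 13 ER stress genes fell. In the matrix list 9 rose and 1 fell, and in the hypoxia list 7 rose and 2 fell. In the glycolysis list 3 rose and 6 fell, in the NRF2 list 2 rose and 3 fell, and in the mitosis list 3 fell. The lysosome list had 2 up and 2 down, p53 1 up and 2 down, ferroptosis and iron 1 up and 2 down, and integrated stress 3 up and 1 down. TCA, NFkB and mitochondrial mRNA each held 2 genes that rose, pan-reactive 1, and the neuron list 2 that fell.

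The count of 492 genes for lactic acid (305 up, 187 down) became 101 without lactic acid 1, 106 without lactic acid 2, 110 without lactic acid 3, 220 without control 2 and 1972 (1106 up, 866 down) without control 1. The latter became 1095 up and 1192 down with the replicate block and 1291 and 1505 with the length trend removed. A limma fit of only these 6 libraries called 0 genes, with 1672 at an unadjusted p under 0.05 (2832 in the 12-library fit), while median-of-ratios scaling gave 825 and leaving out mitochondrial and the 10 most abundant genes gave 951.

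Low-NaHCO3 medium, against control, raised all 24 of 24 members of the interferon list, the same number adjusted over the list alone. Ifit3 (ENSMUSG00000074896) stood at 234 ± 25.3 against 8.61 ± 5.35 TPM, log2 change 4.75 ± 0.34, adjusted p = 2.07e-06. Ifi44 stood at 37.1 ± 5.93 against 0.609 ± 0.201 TPM, log2 change 4.56 ± 0.22, adjusted p = 2.76e-07. Irf7 (50.2 against 2.89 TPM, log2 change 3.72 ± 0.22), Usp18 (50.1 against 2.33 TPM, log2 change 3.93 ± 0.19), Xaf1 (3.65 ± 0.16), Ifit3b (4.07 ± 0.28) and Oasl2 (3.64 ± 0.31) are in the list. Oas3 (4.25 ± 0.21), Trim34a (3.92 ± 0.22) and Phf11d (3.85 ± 0.14), further interferon-inducible genes, were also among the 10 highest. The list had a median log2 change of 3.28, adjusted p = 6.39e-21. It had adjusted p = 0.186 with an estimated correlation, and its median without control 1 was 3.35. The chemokine Cxcl10 (42.9 against 3.15 TPM, log2 change 3.41 ± 0.19) belongs to this list and to the pan-reactive one. Of 7 A1-type genes 5 rose and 1 fell, the same adjusted over the list alone. The largest rises there were those of the interferon-inducible genes Gbp2 (52.0 against 3.61 TPM, log2 change 3.60 ± 0.27), Iigp1 (2.69 ± 0.31), H2-T23 (1.49 ± 0.34) and H2-D1 (1.19 ± 0.18).

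**Figure D3:**
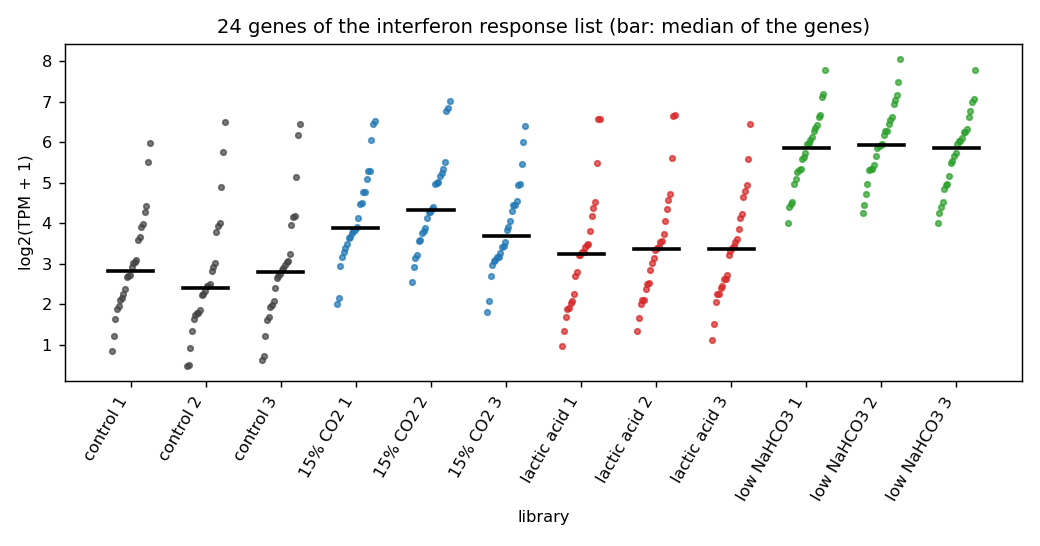
Level of the 24 interferon list genes in each library as log2(TPM + 1), by group; each point is 1 gene and the bar is the median of the library. Low-NaHCO3 libraries lie highest and 15% CO2 libraries above both other groups, with median log2 changes against control of 3.28 and 1.34.

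Immediate early, matrix, ER chaperone and mitosis genes rose in low-NaHCO3 medium. Txnip (ENSMUSG00000038393), the thioredoxin-interacting protein that limits glucose uptake, rose (169.8 ± 22.1 against 18.4 ± 10.5 TPM, log2 change 3.26 ± 0.30, adjusted p = 9.43e-06). Of 25 matrix genes 11 rose and 4 fell, with Ccn1 among those that rose (1618 ± 63.8 against 197 ± 57.5 TPM, log2 change 3.08 ± 0.18, adjusted p = 5.82e-07). Of 18 immediate early genes 10 rose and 1 fell. The largest rises were those of Zfp36 (49.3 against 10.1 TPM, log2 change 2.18 ± 0.14), Fosl1 (138 against 40.8 TPM, log2 change 1.78 ± 0.19), Egr1 (199.6 against 69.3 TPM, log2 change 1.77 ± 0.37) and Fosb (1.64 ± 0.55, and 2.52 without control 1). Of 20 ER stress genes 12 rose and none fell. Hspa5, the ER chaperone BiP, led them (3494 ± 235 against 1074 ± 269 TPM, log2 change 1.73 ± 0.20, adjusted p = 3.97e-05), with Manf (252 against 116 TPM, log2 change 1.11 ± 0.12), Pdia6 (0.999 ± 0.17) and Hyou1 (0.79 ± 0.14). Of 24 mitosis genes 19 rose, 20 adjusted over the list alone. Among them were the centromere histone gene Cenpa (337 ± 15.6 against 87.0 ± 29.8 TPM, log2 change 2.01 ± 0.22, adjusted p = 2.87e-05), Kif23 (1.45 ± 0.18), Top2a (750.0 against 329 TPM, log2 change 1.25 ± 0.22) and Tpx2 (1.10 ± 0.20). The mitosis median was 0.81, and 0.49 without control 1. Of 16 NFkB genes 8 rose and 4 fell. The chemokine gene Ccl5 (22.9 against 4.63 TPM, log2 change 2.14 ± 0.27), Tnfaip3 (1.97 ± 0.14) and Relb (1.48 ± 0.13) rose, and Ccl2 fell (−0.60 ± 0.22), a call that median-of-ratios scaling ended.

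Lipid synthesis genes fell in low-NaHCO3 medium. Of 24 cholesterol genes 15 fell, while adjusted over the list alone 17 fell and 1 rose. Among those that fell were Acat2 (19.1 ± 0.597 against 63.5 ± 8.15 TPM, log2 change −1.67 ± 0.15, adjusted p = 6.86e-06), Sqle (−1.53 ± 0.10) and Mvk (−1.48 ± 0.16). Of 12 fatty acid genes 8 fell, led by Scd2 (249 ± 19.1 against 1229 ± 74.1 TPM, log2 change −2.30 ± 0.10, adjusted p = 1.76e-07) and Elovl6 (13.9 against 62.4 TPM, log2 change −2.09 ± 0.077), with Acaca (−0.92 ± 0.096) and Fads2 (−0.77 ± 0.09). The lowest gene of all was Igfbp5 (3.49 ± 0.0863 against 89.1 ± 38.9 TPM, log2 change −4.24 ± 0.29, adjusted p = 1.6e-06). Gdf11, a growth factor of the TGF-beta family, was among the 10 lowest (8.12 against 74.1 TPM, log2 change −3.04 ± 0.098). Without control 1 the other 8 of these had smaller negative log2 changes. They went from −3.75 to −2.36 for Cend1, −3.52 to −1.65 for Agap2, −3.34 to −1.94 for Fabp7 and −3.28 to −1.24 for Ppp2r2c. For Sncb they went from −3.24 to −1.36, for Tubb4a from −3.19 to −2.06, for Ppp2r2b from −3.12 to −1.97 and for Kcnj4 from −3.03 to −1.22. With control 1 left out, Myog (−2.82 ± 0.22), the connexin gene Gjc3 (−2.81 ± 0.11) and the receptor gene Erbb3 (−2.67 ± 0.099) were among the 10 lowest, with the log2 changes of that fit. Slc7a11, the cystine transporter of the integrated stress, NRF2 and ferroptosis lists, fell (1.89 against 16.4 TPM, log2 change −2.60 ± 0.12).

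Acid-base, glycolysis and hypoxia genes moved both ways in low-NaHCO3 medium. In the acid-base list 4 of 19 rose and 7 fell. Slc4a7 (71.4 against 27.6 TPM, log2 change 1.34 ± 0.10), the monocarboxylate transporter gene Slc16a4 (42.5 against 16.9 TPM, log2 change 1.29 ± 0.15) and Car9 (13.1 against 6.71 TPM, log2 change 0.87 ± 0.099) rose, and Slc4a2 fell (9.72 against 26.8 TPM, log2 change −1.36 ± 0.14). In the glycolysis list 1 of 18 rose and 6 fell. The glucose transporter gene Slc2a1 (41.5 against 86.5 TPM, log2 change −1.03 ± 0.13) fell. Eno1 (−0.85 ± 0.20), Pfkl (−0.72 ± 0.16) and Ldha (−0.69 ± 0.20) fell too. In the hypoxia list 6 of 23 rose, with Ndrg1 (1.92 ± 0.38), and 10 fell, with Egln3 (−1.89 ± 0.17). Of 13 mitochondrially encoded mRNAs 8 fell, with mt-Nd1 (7708 against 41573 TPM, log2 change −2.43 ± 0.41), mt-Nd3 (−2.40 ± 0.19), mt-Nd4l (−2.10 ± 0.22) and mt-Nd4 (−1.59 ± 0.28) lowest. Of 30 ribosomal protein genes 17 rose, Rpl10 (0.88 ± 0.28) and Rps3 (0.80 ± 0.29) among them. Without control 1, 6 rose and Rps3 did not pass (0.59).

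Camera called 11 lists for low-NaHCO3 medium, 8 of them up, and none with an estimated correlation. Beside interferon they were mitosis (median 0.81, adjusted p = 1.97e-07), ribosomal protein (median 0.67, adjusted p = 2.17e-05), ER stress (median 0.56, adjusted p = 2.21e-05), immediate early (median 0.90, adjusted p = 0.000154) and cholesterol (median −0.65, adjusted p = 0.00117). With an estimated correlation these had adjusted p = 0.598, 0.72, 0.588, 0.122 and 0.588. The rest were A1-type (median 1.19, adjusted p = 0.012), NFkB (median 0.29, adjusted p = 0.0264), matrix (median 0.28, adjusted p = 0.0295), fatty acid synthesis (median −0.62, adjusted p = 0.0463) and mitochondrial mRNA (median −1.09, adjusted p = 0.0463). They had adjusted p = 0.588, 0.588, 0.588, 0.588 and 0.743 with an estimated correlation. Without control 1 the NFkB, fatty acid and mitochondrial mRNA lists no longer passed. The immediate early list then had adjusted p = 0.0156 with an estimated correlation.

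The other 15 lists tested for low-NaHCO3 medium had adjusted p from 0.0662 to 0.993. In the lysosome list 10 of 32 rose and 6 fell, with Hexa at 1.46 ± 0.14 and Neu1 at −1.63 ± 0.10 on the log2 scale. In the DNA replication list 7 of 26 rose, with Dtl (1.20 ± 0.19), and 5 fell, with Tyms (−1.14 ± 0.22). In the NRF2 list 7 of 20 rose, with Abcc1 (1.36 ± 0.17), and 5 fell, with G6pdx (−1.04 ± 0.13). In the integrated stress list 4 of 25 rose, with Nupr1 (1.16 ± 0.22), and 8 fell, with Atf5 (−1.80 ± 0.19). In the ferroptosis and iron list 4 of 17 rose, with the ferritin gene Fth1 (0.64 ± 0.17), and 7 fell. In the TCA list 4 of 27 rose and 8 fell, with Suclg1 (−1.21 ± 0.12). In the p53 list 4 of 18 rose, with Plk2 (1.09 ± 0.18), and 4 fell, with Bax (−1.04 ± 0.16). The heat shock list had 1 of 16 up, Cryab (1.04 ± 0.17), and 5 down, with Hsph1 (−1.22 ± 0.069). The pan-reactive list had 3 of 9 up and 2 down, with Serpina3n (−1.80 ± 0.15), and the A2-type list 3 of 5 up, with Clcf1 (2.01 ± 0.20), and 1 down. Nfia was the 1 astrocyte identity gene of 10 that fell (−0.65 ± 0.19), a call that both scalings ended. Counts adjusted over the list alone were the same except 3 up for TCA, 5 down for integrated stress, 3 up for p53, 6 up for DNA replication and 0 for astrocyte identity. Median, mean and test differed in sign in the hypoxia, TCA, ferroptosis, p53 and pan-reactive lists.

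Without control 1 the DNA replication list in low-NaHCO3 medium had 6 up and 10 down, its median going from 0.25 to −0.044. Integrated stress then had 17 genes that fell, NRF2 8, and heat shock 11, with 3 that rose. In the glycolysis list 2 rose. Astrocyte identity had 2 up and 3 down, and pan-reactive 1 down. No A1-type gene fell, and 1 cholesterol gene rose and 1 ER stress gene fell. Proton sensing held 2 genes that rose and 2 that fell, and microglia 2 that rose.

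Some markers of other cell types fell in low-NaHCO3 medium. Of those named here, control 1 held higher levels of Olig1, Cnp, Olig2, Tubb3, Nefl, Asic1 and Tmem119 than controls 2 and 3. Of 8 oligodendrocyte lineage genes 5 fell. The log2 change was −2.52 ± 0.51 for Olig1 (−1.70 without control 1), −2.43 ± 0.45 for Cnp (−1.72) and −1.32 ± 0.43 for Olig2 (−0.71). Of the lists too small for camera, neuron held Tubb3 (−0.82 ± 0.29, −0.40 without control 1) and Nefl (−1.91 ± 0.72, −0.75), which fell, calls that median-of-ratios scaling ended. Microglia held Cd68, which rose (0.88 ± 0.18), and Tmem119, which fell (−2.39 ± 0.30). The endothelial and mural list held Acta2, which rose (1.08 ± 0.21), and Pdgfrb, which fell (−0.63 ± 0.11). Proton sensing held Asic3, which rose (1.34 ± 0.19), and Asic1, which fell (−2.03 ± 0.45, −1.34 without control 1).

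The count of 6758 genes for low-NaHCO3 medium (2442 up, 4316 down) was 7786 (2781 up, 5005 down) without control 1. The balance was 3468 up and 3362 down under median-of-ratios scaling and 3078 and 2708 under quantile normalization. It was 3690 and 2924 with the length trend removed and 2148 and 5095 without mitochondrial and top 10 genes.

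**Figure D4:**
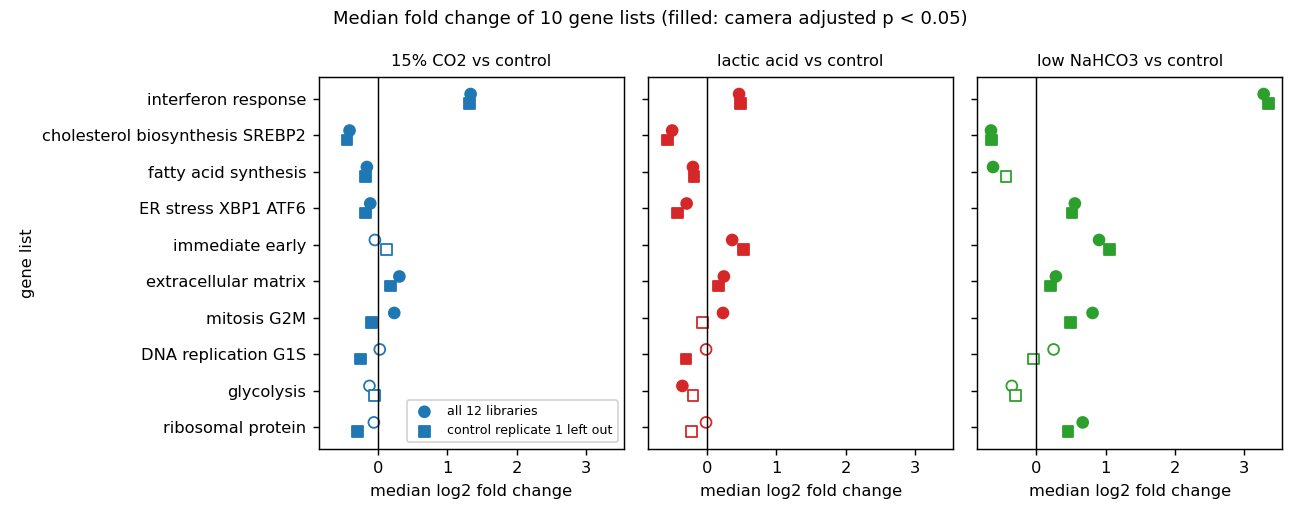
Median log2 change of 10 gene lists in the 3 treatments against control, 1 panel each, for all 12 libraries (circles) and with control 1 left out (squares); filled symbols passed camera at an adjusted p of 0.05. The interferon list lies at 1.34, 0.46 and 3.28 for 15% CO2, lactic acid and low-NaHCO3 medium, and the cholesterol list at −0.41, −0.50 and −0.65.

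Between 15% CO2 and lactic acid, 25 genes differed. Myog (ENSMUSG00000026459) was among the highest under 15% CO2, at 31.0 ± 3.21 against 4.71 ± 1.74 TPM, log2 change 2.52 ± 0.22, adjusted p = 0.00154. The cardiac actin gene Actc1 (34.5 against 9.03 TPM, log2 change 1.83 ± 0.19), Klhl41 (20.6 against 4.74 TPM, log2 change 1.96 ± 0.23), Asb2 (9.51 against 2.31 TPM, log2 change 1.68 ± 0.22) and Mymk (12.5 against 4.73 TPM, log2 change 1.29 ± 0.20) went the same way. Ifit1 was also higher under 15% CO2 (25.1 against 7.76 TPM, log2 change 1.57 ± 0.23) and was 1 of 2 interferon genes of 24 that passed, 22 adjusted over the list alone. Lactic acid had the higher values of Sh2d6 (4.51 against 16.8 TPM, log2 change −1.70 ± 0.19), Cd68 (93.4 against 215 TPM, log2 change −1.19 ± 0.18), Akr1c18 (−0.98 ± 0.16) and Tmem74 (−0.70 ± 0.1). Camera called 8 lists. Interferon was higher under 15% CO2 (median 0.86, adjusted p = 3.46e-25, and adjusted p = 0.117 with an estimated correlation). Immediate early was lower (median −0.43, adjusted p = 6.03e-10, and adjusted p = 0.00739 with an estimated correlation), the 1 call that held, although 0 of its 18 members passed over all genes and 1 adjusted over the list alone. The others were integrated stress (median −0.28, adjusted p = 1.23e-09), ER stress (median 0.23, adjusted p = 0.00014), heat shock (median 0.17, adjusted p = 0.00122), cholesterol (median 0.15, adjusted p = 0.00925), NRF2 (median −0.081, adjusted p = 0.0114) and ribosomal protein (median −0.057, adjusted p = 0.0305). With an estimated correlation these had adjusted p = 0.622, 0.622, 0.493, 0.639, 0.744 and 0.902. The count of 25 was 9 without CO2 1, 6 without CO2 2, 8 without lactic acid 1, 8 without lactic acid 2 and 563 without control 1, which is in neither group and enters through the shared spread. The 563 stand beside 1399 genes for a split of the same 6 libraries that set CO2 1, CO2 3 and lactic acid 3, which have the highest summed mitochondrial mRNA (203698, 248003 and 278249 TPM), against the others (156010 to 164300 TPM). In the fit without control 1, 16 interferon genes were higher under 15% CO2 and 10 immediate early genes lower, and the p53 and A2-type lists also passed camera as lower (adjusted p = 0.518 and 0.287 with an estimated correlation). The 563 became 166 without CO2 1, 251 without CO2 2, 169 without lactic acid 1 and 183 without lactic acid 2.

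Between 15% CO2 and low-NaHCO3 medium, 6318 genes differed (4157 higher and 2161 lower under 15% CO2). Igfbp5 (263 ± 12.6 against 3.49 ± 0.0863 TPM, log2 change 5.88 ± 0.29, adjusted p = 3.32e-07), Myog (31.0 against 0.527 TPM, log2 change 4.40 ± 0.22) and Gas1, a growth arrest gene (23.3 against 1.28 TPM, log2 change 3.43 ± 0.17), were highest under 15% CO2. Klhl41 (3.42 ± 0.23), Islr (3.29 ± 0.37) and Tle2 (3.15 ± 0.28) followed. Among the 6 lowest under 15% CO2 was the histone gene Hist1h4i (ENSMUSG00000060639), at 25.8 ± 11.4 against 277 ± 66.8 TPM, log2 change −3.44 ± 0.37, adjusted p = 2.57e-05. Hist3h2ba (−3.65 ± 0.75), Hist1h2bg (−3.06 ± 0.31), Hist1h2bc (−2.98 ± 0.40), Oas3 (−3.37 ± 0.21) and the neuropeptide gene Vgf (−2.94 ± 0.83) went the same way. Of 24 interferon genes 23 were lower under 15% CO2 (median −1.60, adjusted p = 4.78e-15, and adjusted p = 0.387 with an estimated correlation). Camera called 6 lists, of which 1 was higher under 15% CO2. Lower were also ER stress (12 of 20 genes, median −0.57, adjusted p = 7.61e-07), ribosomal protein (14 of 30, median −0.66, adjusted p = 7.61e-07), mitosis (15 of 24, median −0.60, adjusted p = 3.68e-06) and immediate early (11 of 18, with 1 higher, median −0.96, adjusted p = 3.02e-05). Those had adjusted p = 0.653, 0.729, 0.729 and 0.0768 with an estimated correlation. Mitochondrial mRNA was higher (10 of 13, median 1.23, adjusted p = 0.0188, and adjusted p = 0.729 with an estimated correlation). Median-of-ratios scaling turned the balance of all genes to 3040 higher and 3480 lower, the removal of the length trend to 2779 and 3385, and without control 1 there were 8469 genes. In that fit 25 ribosomal protein genes were lower, mitochondrial mRNA no longer passed camera, and immediate early passed with an estimated correlation too (adjusted p = 0.0167).

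Between lactic acid and low-NaHCO3 medium, 5981 genes differed (3793 higher and 2188 lower with lactic acid). Highest with lactic acid were Igfbp5 (116 against 3.49 TPM, log2 change 4.63 ± 0.29), P2rx3 (18.1 ± 1.39 against 1.10 ± 0.675 TPM, log2 change 3.23 ± 0.22, adjusted p = 2.01e-06) and Grem1, an inhibitor of bone morphogenetic proteins (114 against 17.5 TPM, log2 change 2.63 ± 0.12). Slc35g1 (2.81 ± 0.19), Gdf11 (2.79 ± 0.098) and Gjc3 (2.69 ± 0.10) were among them too. Lowest were Hist1h4i (16.2 against 277 TPM, log2 change −4.05 ± 0.37), Ifit3 (−3.96 ± 0.34), Ifit3b (−3.94 ± 0.28), Ifi44 (−3.73 ± 0.22), Oas3 (−3.71 ± 0.21) and Hist3h2ba (−3.69 ± 0.75). Camera called 7 lists, of which 1 was higher with lactic acid. Of 24 interferon genes 23 were lower (median −2.53, adjusted p = 7.53e-20, and adjusted p = 0.316 with an estimated correlation). Lower were also ER stress (15 of 20 genes, median −0.79, adjusted p = 1.11e-08), mitosis (13 of 24, median −0.54, adjusted p = 1.07e-05), ribosomal protein (13 of 30, but 0 adjusted over the list alone, median −0.64, adjusted p = 1.35e-05), immediate early (9 of 18, with 2 higher, median −0.72, adjusted p = 0.0124) and A1-type (4 of 7, median −0.73, adjusted p = 0.041). With an estimated correlation these had adjusted p = 0.41, 0.874, 0.874, 0.316 and 0.832. Mitochondrial mRNA was higher (10 of 13, median 1.34, adjusted p = 0.00823, and adjusted p = 0.874 with an estimated correlation). Median-of-ratios scaling turned the balance of all genes to 2861 higher and 3339 lower, the removal of the length trend to 2642 and 3180, and without control 1 there were 8239 genes. In that fit 21 mitosis and 21 ribosomal protein genes were lower, and integrated stress (higher) and DNA replication (lower) also passed camera (adjusted p = 0.718 and 0.718 with an estimated correlation).

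**Figure D5:**
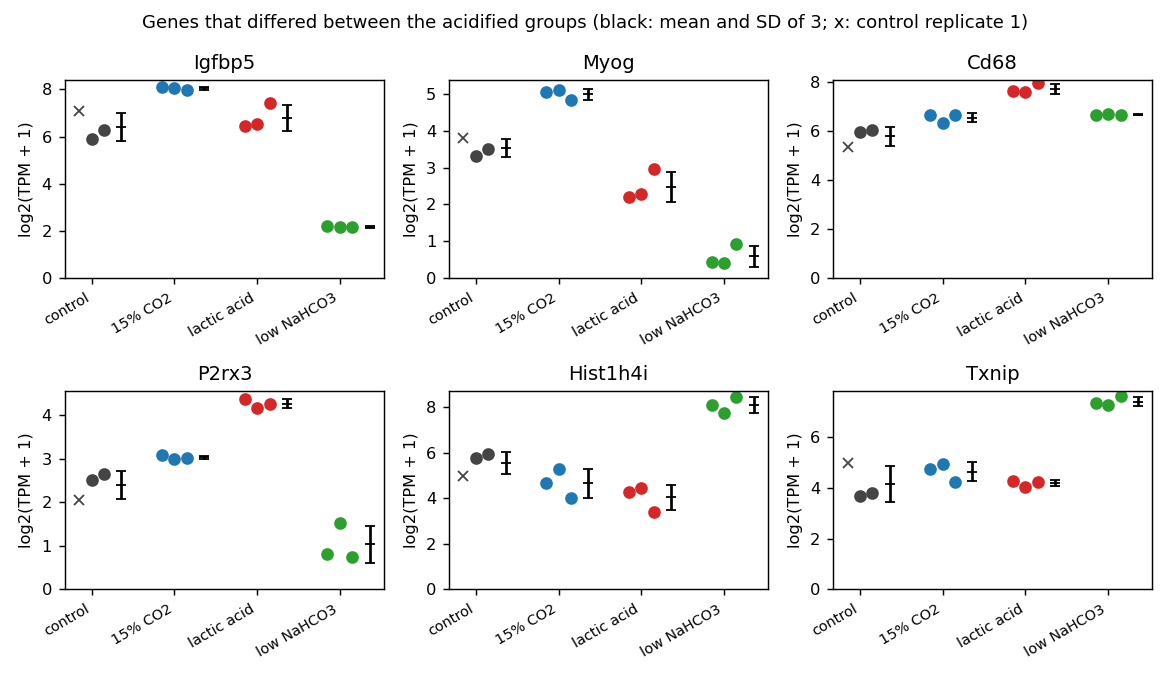
Levels of Igfbp5, Myog, Cd68, P2rx3, Hist1h4i and Txnip in each library as log2(TPM + 1), by group; crosses mark control 1 and the black marks are the mean and SD of 3 libraries. Igfbp5 and Myog were highest under 15% CO2 and lowest in low-NaHCO3 medium, Cd68 and P2rx3 highest with lactic acid, and Hist1h4i and Txnip highest in low-NaHCO3 medium.

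All 3 treatments moved 49 genes in the same direction, 43 up and 6 down. Log2 changes are given here in the order 15% CO2, lactic acid and low-NaHCO3 medium. The 6 genes up with the largest smallest change were Rtp4 (1.97, 1.10 and 3.47), Odf3l1 (1.33, 1.97 and 1.37), Oas1b (1.80, 1.16 and 3.29), Ifi203 (1.31, 0.96 and 1.63), Mndal (1.22, 0.98 and 1.94) and Trim30d (1.07, 0.95 and 2.72). All but Odf3l1 are known as interferon-inducible genes or their close relatives. Car9, of the fixed panel, rose in each as well (0.94, 0.63 and 0.87). The 6 down were Tfrc (−0.82, −1.29 and −0.47), Mt1 (−0.57, −0.95 and −1.19), Cyp51 (−0.66, −0.87 and −0.65), Elovl6 (−0.502, −0.63 and −2.09), Shroom2 (−0.49, −0.72 and −2.08) and Dynll1 (−0.40, −0.77 and −1.71). Median-of-ratios scaling ended the call of Tfrc in low-NaHCO3 medium. Independent lists of these sizes would share 0.77 up and 0.042 down. The count of 49 was 5, 15 and 21 without CO2 1, 2 and 3 in turn, 27 and 18 without lactic acid 1 and 2, 29 without low-NaHCO3 1, 11 without control 2 and 335 without control 1 (225 up, 110 down). The 335 became 15 without control 2, 68 without control 3, 144 without CO2 1, 205 without CO2 3, 223 without low-NaHCO3 1 and 530 without lactic acid 3. The 49 became 19 with the replicate block and 109 without mitochondrial and the 10 most abundant genes.

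15% CO2 and lactic acid shared 60 genes up and 7 down, with 1 opposite, where independent lists would share 3.91 up and 0.12 down. 15% CO2 and low-NaHCO3 medium shared 102 up and 6 down with 33 opposite (31.3 and 2.80 for independent lists). Lactic acid and low-NaHCO3 medium shared 187 up and 138 down with 52 opposite (60.4 and 65.5). Without control 1 the pairs shared 406 up and 141 down with 4 opposite (64.3 and 13.5 for independent lists), 321 up and 130 down with 238 opposite (162 and 78.2), and 528 up and 621 down with 317 opposite (252 and 355). Across genes, which are not independent replicates, log2 changes of 15% CO2 and lactic acid had a Pearson r of 0.82, against 0.46 and 0.53 for each with low-NaHCO3 medium. Because the control libraries are shared, simulated unchanged groups already gave an r of about 0.50. These simulations gave every library the same spread per gene. In the data the SD of log2 differences was 0.976 and 0.968 for control 1 with controls 2 and 3. It was 0.189 between controls 2 and 3 and 0.176 to 0.323 between replicates of a treatment. The simulated r and covariance for all 12 libraries are therefore too low, and an excess over them cannot be read as a shared response. Without control 1 r was 0.72, 0.22 and 0.32, where unchanged groups would give about 0.60. The covariances were 0.116, 0.135 and 0.167 against 0.029 in simulations, and without control 1 they were 0.065, 0.046 and 0.074 against 0.014. The 3 controls cannot be divided into separate sets of 2, so part of the excess, in shared genes as in covariances, may stem from them.

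In the fixed panel, Mki67, a proliferation marker, had log2 change 0.56 ± 0.22, adjusted p = 0.0506 in low-NaHCO3 medium and log2 change 0.41 ± 0.22, adjusted p = 0.405 under 15% CO2. Without control 1 these log2 changes were 0.27 and 0.11. Vim rose in low-NaHCO3 medium (2507 against 1589 TPM, log2 change 0.71 ± 0.23, 0.41 without control 1), a call that quantile normalization ended. Hmgcs1 fell there (−0.51 ± 0.20), a call lost under median-of-ratios scaling and without control 1 (−0.29). Under 15% CO2 Hmgcs1 had log2 change −0.87 ± 0.20, adjusted p = 0.0625, and passed without control 1 (−0.65). Txnip had log2 change 0.49 ± 0.30, adjusted p = 0.457 under 15% CO2 and log2 change 0.032 ± 0.30, adjusted p = 0.959 with lactic acid. Control 1 held 30.5 TPM of it, against 11.8 and 12.9 TPM in controls 2 and 3, and without control 1 the log2 changes were 0.91, which passed, and 0.45, which did not. Under 15% CO2 Slc16a1, a lactate transporter, had log2 change 0.031 ± 0.19, adjusted p = 0.948. Cdkn1a (log2 change −0.049 ± 0.16, adjusted p = 0.897) and S100b (log2 change −0.45 ± 0.35, adjusted p = 0.542) did not pass there either. Without control 1 the direction of all 3 turned and none passed (−0.17, 0.066 and 0.096). Ldha, lactate dehydrogenase A, had log2 change −0.54 ± 0.20, adjusted p = 0.136 with lactic acid, and passed without control 1 (−0.78). The glutamate transporter Slc1a3, the lactate exporter Slc16a3 and the proton-sensing receptors Gpr4 and Gpr65 were too low to test. Slc1a3 was at 0 to 0.0210 TPM outside control 1, Slc16a3 at no more than 0.873 TPM and Gpr65 at no more than 0.195 TPM. Gpr4 was at no more than 0.640 TPM outside control 1.

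Summed mitochondrially encoded mRNA was 172210 ± 21965 TPM in control, 202570 ± 46007 under 15% CO2, 200606 ± 67288 with lactic acid and 105579 ± 2579 in low-NaHCO3 medium (n = 3 each; exact two-sided permutation p = 0.5, 0.6 and 0.1 against control). Summed ribosomal protein mRNA was 39653 ± 9739, 38950 ± 6304, 41227 ± 10786 and 60215 ± 2110 TPM (exact two-sided permutation p = 0.9, 0.5 and 0.1). Without control 1 the control means were 159684 TPM of mitochondrial and 45256 TPM of ribosomal protein mRNA, so that the ribosomal protein mean with lactic acid lay below control in place of above it. With 3 libraries against 3, p cannot fall under 0.1.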

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

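The contrasts between treatments were set at the start, while the tests chosen only after the result was seen are those of genes outside the naming rule: the contrasts given here for Mymk, Pdgfrb, Creld2, Manf, Dnajc3, Vegfa, Ccl7 and mt-Co2, and the changes under 15% CO2 of Myog, Klhl41, Mymk and Gas1. Each result below met 1 condition: a pair of treatments moved the same gene or list in opposite directions against control, each past its threshold, and the contrast between the 2 treatments passed as well. The condition was applied to each gene named in the text. No technical or biological explanation was tested for them. Groups of 3 libraries are too small for a test of single outlying libraries.

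Between 15% CO2 and low-NaHCO3 medium, the ER stress list went down in the first and up in the second (−0.11 and 0.56), with a difference of −0.57 (camera adjusted p = 7.61e-07, and adjusted p = 0.653 with an estimated correlation). With an estimated correlation the calls against control were lost as well (adjusted p = 0.806 and 0.588). Under 15% CO2 no single member of the 20 passed, over all genes or adjusted over the list alone, and quantile normalization also ended the list's call. Igfbp5 rose by 1.63 and had −4.24 in low-NaHCO3 medium, a difference of 5.88 (adjusted p = 3.32e-07). Myog, Klhl41 and Mymk went the same way, with differences of 4.40 for Myog (adjusted p = 3.42e-07), 3.42 for Klhl41 (adjusted p = 1.61e-06) and 2.06 for Mymk (adjusted p = 1.27e-05). Gas1 rose by 0.82 under 15% CO2 and had −2.61 in low-NaHCO3 medium, a difference of 3.43 (adjusted p = 3.42e-07). The growth factor receptor gene Pdgfrb differed by 1.28 (adjusted p = 7.86e-06). Between 15% CO2 and lactic acid, Myog rose in the first and fell in the second (1.46 and −1.06), a difference of 2.52 (adjusted p = 0.00154).

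Between lactic acid and low-NaHCO3 medium, the ER stress list differed by −0.79 (camera adjusted p = 1.11e-08, and adjusted p = 0.41 with an estimated correlation), from −0.30 in the first and 0.56 in the second. The calls against control had adjusted p = 0.526 and 0.588 with an estimated correlation. Its members Creld2 (−1.78, adjusted p = 2.09e-05), Manf (−1.85, adjusted p = 1.41e-06) and Dnajc3 (−1.08, adjusted p = 7.13e-06) fell with lactic acid and rose in low-NaHCO3 medium. The histone gene Hist1h4i did so too (−4.05, adjusted p = 1.05e-05). P2rx3 (3.23, adjusted p = 2.01e-06), Grem1 (2.63, adjusted p = 3.91e-07), Pdgfrb (1.09, adjusted p = 2.63e-05) and Vegfa (1.22, adjusted p = 8.18e-06) went up with lactic acid and down in low-NaHCO3 medium. So did Ccl7 (1.24, adjusted p = 0.000141) and mt-Co2 (1.48, adjusted p = 5.53e-05).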

How the results depend on the processing

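The tests chosen only after the results were seen were the removal of the length trend, the joint omission of 3 libraries, the omission of single libraries for gene lists and summed TPM, the omission of control 1 for contrasts between treatments, and every repeat of a count with control 1 left out. All settings fixed at the start were run. Counts for low-NaHCO3 medium against control and against the other treatments, and the F test count, stayed within 1.5 times under each setting run. Of 254 gene results named in the text that passed with all 12 libraries or without control 1, none changed direction under any setting run. The other 6 named, which passed in neither, were not followed across settings. No longer past the threshold were 41 without a filter, 36 with the replicate block, 25 under quantile normalization, 9 without a trend, 8 under median-of-ratios scaling, 5 of 247 without mitochondrial and top 10 genes, 4 with log2(TPM + 0.1) and 3 with robust eBayes. The 248 that the stricter filter still tested all kept their side. Without control 2, 47 of 211 no longer passed, without CO2 1 31 of 58 and without lactic acid 2 40 of 94. Without control 1, 2 no longer passed and 3 newly did. Of 12-library list calls, estimated correlations ended 51 and left 1. Depth is unknown and its effect on low genes was not tested. Unless stated, the cause of a shift was not tested.

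For 15% CO2 (166 genes) the count was 316 without mitochondrial and top 10 genes, 72 with the replicate block, 0 with only the groups compared (limma, 1177 at an unadjusted p under 0.05), 1609 with control 1, CO2 3 and lactic acid 3 left out, and 30 (without CO2 1) to 902 (without control 1) leaving out 1 library, with 35 and 92 without CO2 2 and 3 and 47 without control 2. For lactic acid (492) it was 825 under median-of-ratios scaling, 951 without mitochondrial and top 10 genes, 0 with only the groups compared (limma, 1672 at an unadjusted p under 0.05), 2275 with the 3 libraries left out, and 101 (without lactic acid 1) to 1972 (without control 1), with 106 and 110 without lactic acid 2 and 3 and 220 without control 2. The fit of only the groups compared keeps control 1 and loses the other groups' estimate of the spread by construction. Between 15% CO2 and lactic acid (25) it was 12 without a filter, 43 with the stricter filter, 43 under median-of-ratios scaling, 40 without a trend, 13 with the block, 40 with the length trend removed, 115 with only the groups compared, and 6 (without CO2 2) to 563 (without control 1), with 9 without CO2 1 and 8 each without lactic acid 1 and 2. For all 3 treatments (49) it was 74 under median-of-ratios scaling, 109 without mitochondrial and top 10 genes, 19 with the block, and 5 (without CO2 1) to 335 (without control 1), with 15 and 21 without CO2 2 and 3, 27 and 18 without lactic acid 1 and 2, 29 without low-NaHCO3 1 and 11 without control 2.

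With control 1 left out, 15% CO2 (902) gave 1357 under median-of-ratios scaling, 1462 without mitochondrial and top 10 genes, 1514 with the length trend removed, and 56 (without control 2) to 624 (without CO2 2), with 206 without control 3 and 345 and 554 without CO2 1 and 3. Lactic acid (1972) gave 970 with only the groups compared, and 229 (without control 2) to 1772 (without lactic acid 3), with 442 without control 3. Where 1 control is left, it is assumed to vary like the other groups. The 2 treatments against each other (563) gave 914 under quantile normalization, 940 with the length trend removed, 116 with only the groups compared, and 166 (without CO2 1) to 728 (without lactic acid 3), with 251 without CO2 2 and 169 and 183 without lactic acid 1 and 2. All 3 treatments (335) gave 541 under median-of-ratios scaling, 506 without mitochondrial and top 10 genes, 592 with the length trend removed, and 15 (without control 2) to 530 (without lactic acid 3), with 68 without control 3, 144 and 205 without CO2 1 and 3 and 223 without low-NaHCO3 1.

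Correlations and covariances across genes are listed where they moved by over 1 SD of their leave-one-out values, a limit chosen after seeing the data. For 15% CO2 with lactic acid r was 0.772 with log2(TPM + 0.1), 0.914 without a filter and 0.720 to 0.897 leaving out 1 library, and the covariance 0.210 without a filter and 0.0653 to 0.221 leaving out 1. For 15% CO2 with low-NaHCO3 medium r was 0.603 without a filter and 0.218 to 0.601 leaving out 1, and the covariance 0.194 with log2(TPM + 0.1), 0.215 without a filter and 0.0459 to 0.259 leaving out 1. For lactic acid with low-NaHCO3 medium r was 0.647 without a filter and 0.324 to 0.643 leaving out 1, and the covariance 0.243 with log2(TPM + 0.1), 0.236 without a filter and 0.0739 to 0.294 leaving out 1. Each lowest value was that without control 1.

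Lists called with an estimated correlation by limma's camera numbered 0, 0 and 0 for 15% CO2, lactic acid and low-NaHCO3 medium, 1 for 15% CO2 against lactic acid, and 0 and 0 for each against low-NaHCO3 medium. For 15% CO2 against low-NaHCO3 medium quantile normalization called 10, and for 15% CO2 against control leaving out 1 library gave 5 (without CO2 2) to 15 (without control 1). Among the 66 list results that passed with all 12 libraries or without control 1, the direction of the list test turned in these cases, given by list medians. Lists that passed in neither were not followed. Under 15% CO2 it turned under quantile normalization for integrated stress (0.0353) and DNA replication (0.0791). Leaving out 1 library gave integrated stress −0.281 to 0.120, DNA replication −0.248 to 0.174, NRF2 −0.236 to 0.0507, mitosis −0.0917 to 0.394, astrocyte identity −1.21 to 0.290 and ribosomal protein −0.293 to 0.103 (0.0745 without control 2, where it turned). With lactic acid it gave DNA replication −0.305 to 0.133, mitosis −0.0644 to 0.391 and astrocyte identity −1.48 to 0.479. Control 1 turned mitosis and astrocyte identity, and control 2, control 3, CO2 2 or lactic acid 3 the others.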

Other observations

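The tests here of control replicate 1, the interferon and cholesterol lists, and splits without control 1 were chosen only after the results were seen. The other splits were set before. Outside control 1 the line had little of several astrocyte genes, chosen here after their values were seen. Slc1a3 was at 0 to 0.0210 TPM, Gfap, the astrocyte filament gene, at 0.126 to 1.19 TPM, Aqp4 at 0 to 0.356 TPM and Aldoc at 0.163 to 0.982 TPM. S100b stood at 33.5 to 49.8 TPM, Sox9 at 31.2 to 52.5 TPM and Vim at 1327 to 2678 TPM. Muscle regulators and structural genes were chosen in the same way. Myf5, an early muscle regulator, stood at 44.97 to 146 TPM, Myod1 at 8.42 to 28.8 TPM, and Myog at 0.335 to 33.3 TPM. The desmin gene Des stood at 12.4 to 27.7 TPM, Actc1 at 7.67 to 36.4 TPM, Mymk at 2.11 to 13.2 TPM and Klhl41 at 0.890 to 24.3 TPM. In low-NaHCO3 medium Myog and Klhl41 reached no more than 0.892 and 1.16 TPM. These values put the astrocyte label of the line in doubt, but no test of cell identity was run.

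Control replicate 1 stands apart from the other 11 libraries. Deeper sequencing of that library is argued against by 220 genes at 50 TPM or more there and under 1 TPM in each other library, among them Snap25 (chosen after its value was seen) at 603 TPM. A library made wholly from brain tissue is argued against by the mitosis list, whose median ratio to controls 2 and 3 is 0.520 (quartiles 0.508 to 0.536), where RNA with none from the line was set to stay under 0.1. RNA of brain tissue mixed with RNA of the line is a candidate explanation: 92.3% of the neuron list, of which controls 2 and 3 each held 4 of 13 genes at 1 TPM or more, is higher there than in every other library, and genes at 100 TPM or more in controls 2 and 3 (1765) have a median ratio of 0.753 (quartiles 0.644 to 0.909). Where such mixing would have taken place stays open, and no biological explanation was tested.

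The interferon list was higher under 15% CO2 and in low-NaHCO3 medium than in control, but passed in neither with an estimated correlation (adjusted p = 0.09 and 0.186). Control 1 as the sole cause is argued against by medians without it of 1.32 (quartiles 1.08 to 1.79) and 3.35 (2.23 to 3.75). RNA of immune cells is argued against by the microglia list, of which 2 genes reached 5 TPM under 15% CO2 (Cd68 up to 99.9 and Tmem119 up to 9.84 TPM, both also in controls) and 1 in low-NaHCO3 medium (Cd68 up to 102 TPM), while C1qa, C1qb, Tyrobp and P2ry12 were listed at 0 in these libraries (these 4 chosen after their values were seen). The scaling of TPM is argued against by medians of at least 1.30 and 3.44 under both other scalings, and reads shared between paralogs as the whole cause by medians of 1.28 (quartiles 0.981 to 1.65) and 3.07 (2.03 to 3.66) over the 12 of 24 members that share under 0.05 of their 25-base stretches with transcripts of other genes. GC content was not tested and stays open, as do the division of reads between near-identical members such as Ifit3 and Ifit3b and a response of the cells to the treatments.

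The cholesterol list was lower under 15% CO2 and with lactic acid, but passed in neither with an estimated correlation (adjusted p = 0.09 and 0.111). A trend of the libraries with transcript length as the whole cause is argued against by medians of −0.517 (quartiles −0.673 to −0.340) and −0.597 (−0.729 to −0.484) with that trend removed and control 1 left out. Control 1 as the sole cause is argued against by medians without it of −0.446 (quartiles −0.594 to −0.331) and −0.574 (−0.720 to −0.505). Other technical explanations, GC content among them, were not tested and stay open, and so does a response of the cells to the treatments.

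Libraries were also split otherwise into groups of the same sizes. Only the real split of 100 drawn gave 6597 genes differing among the 4 groups (next highest 6062). For genes changed in all 3 treatments it gave 49 (next highest 2). Libraries may repeat 1 culture, so chance is not excluded. For contrasts of 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real count of genes and the highest other were 166 and 0 for 15% CO2, 492 and 0 for lactic acid and 6758 and 0 for low-NaHCO3 medium. They were 25 and 0 for 15% CO2 against lactic acid, 6318 and 1 for 15% CO2 against low-NaHCO3 medium and 5981 and 0 for lactic acid against low-NaHCO3 medium. In each of these 6 contrasts only the real split of 10 gave as many. With control 1 left out, 8469 and 1 and 8239 and 0 genes were called for the last 2 contrasts, again as many in 1 of 10. For 15% CO2 against lactic acid without control 1, 2 of 10 splits gave 563 or more, and the other gave 1399. That split sets CO2 1, CO2 3 and lactic acid 3, highest of the 6 in mitochondrial mRNA, against the rest. It points to sample structure beyond the groups. The lists called numbered 11 against at most 13 in other splits for 15% CO2 (5 of 10 splits gave as many), 9 against 15 for lactic acid (8 of 10) and 11 against 15 for low-NaHCO3 medium (7 of 10). They numbered 8 against 7 for 15% CO2 and lactic acid (1 of 10), 6 against 8 for 15% CO2 and low-NaHCO3 medium (5 of 10) and 7 against 7 for lactic acid and low-NaHCO3 medium (2 of 10).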
